A study of Taeniopygia guttata with 21 samples.

How the data were processed

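Expression was measured by RNA sequencing in embryonic skin of wild-type zebra finches at stage HH28. Skin came from 7 locations, 3 dorsal (anterior, saddle and posterior) and 4 ventral (anterior, ventral-most, flank and posterior), with 3 libraries per location and 21 in all. Per the labels' protocols, tissue was kept in RNAlater, total RNA was purified with a column kit for small samples, a small fixed amount was amplified with SMART-Seq v4 (a kit that copies polyadenylated RNA into full-length cDNA), and libraries were built with Nextera XT. Such libraries carry no molecular identifiers, so reads are not independent molecules, and every counting interval or floor given here covers counting error only. The submitters' processing notes name FastQC, Picard, SAMtools, STAR 2.4.0 and DESeq2 without saying what each did. The genome build, the annotation release and the program that counted reads per gene are not given in the sources used here.

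The deposited unit is a signal per gene: read counts divided by a size factor for each library, by the authors, per the file name and the column headers. Every column was a whole multiple of its own smallest step, which lay between 0.78 and 1.37. Dividing by that step gave whole reads for 100.0% of the values in every library, within 0.01 reads. Recovered totals ran from 12.9 to 23.0 M reads per library (M, mega), with a median of 18.6 M. Between 14161 and 15143 genes had at least 1 read in a library, and the gene with the most reads took between 0.96% and 1.3% of a library. No pair of libraries came near to being a duplicate.

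The table listed 18202 genes by FastDB identifier, with coordinates and, for some, names and Entrez identifiers. Coordinates are printed as the table gives them. Symbols were taken from a RefSeq gene table of the assembly bTaeGut7.mat by Entrez identifier, used for names only, and otherwise from the deposited name. This gave 8546 genes a symbol, 8122 from the reference table and 424 from the deposited name alone, and left 9656 without. ZIC1 and KERA are among those named from the deposited name alone. Of 9858 Entrez identifiers 8707 were found. The deposited names had lost the letters NA wherever these occurred. A gene without a symbol was tested and counted, but could be in no gene list and is not named, so a list or a named set covers less than the tissue expressed. NXN has 2 entries in the table that are near-identical copies, and its values are uncertain for that reason.

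Tests were run on log2(value + 1) with limma 3.58.1 in R 4.3.3 (linear models with a mean-variance trend and robust moderation), because the deposited values are normalised and not whole counts. Genes with a value of at least 10 in at least 3 libraries were kept, which left 14005. All 7 locations entered a single fit. A gene is called here when its Benjamini-Hochberg adjusted p from limma was below 0.05, and each adjusted p given is limma's unless another tool is named. Log2 fold changes are differences of mean log2(value + 1) with the standard error (SE) of the fit. The added 1 makes them understate the change of genes with low values. Being based on means of logs, they can also exceed the ratio of the mean levels where libraries vary widely, as for TYR and ZIC1 between dorsal and ventral skin. Levels are means of normalised read counts with the standard deviation (SD) between libraries. The comparisons were any difference among the locations, dorsal against ventral (the mean of 3 locations against the mean of 4), anterior against posterior within each side, the difference between those contrasts, and each location against the mean of the others on its side.

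Gene lists, the comparisons, the alternatives and the rule for naming genes were fixed before the data were examined. For dorsal against ventral the rule took the 10 called genes with the largest fold change in each direction, with 8 in each direction for each anterior-posterior contrast and 4 for the other comparisons, among genes with a symbol, the same sign within each replicate number and a mean log2 value of at least 5 on the higher side. It added the 5 genes with the largest F among all locations, up to 3 called members of each list with the smallest adjusted p, and ASIP, KIT, KITLG, MITF and EDNRB wherever these were measured. MC1R, EDN3 and EDNRB2 belonged to the same set and are not analysed here. Some genes the rule gave are not reported here. Lists covered HOX genes, regulators of dorsal and ventral mesoderm, melanocyte and melanin genes, secreted regulators of melanocytes, feather placode genes, signalling pathways, skin compartments, and markers of other tissues that a piece of skin could carry. A list's members are counted from the test over all genes and, beside it, with p adjusted over the list alone. Lists with 3 or more tested members were also compared with all other genes by camera with a preset correlation between genes of 0.01, adjusted over 29 lists. The list of mitochondrial-encoded genes had too few tested members. Where all libraries of the lower side had 0 reads, the fold is a lower bound computed against 3 reads over that side. With 1 to 3 reads, the ratio sets the mean normalised count of the higher side against the reads of the lower side divided by the sum of its size factors, with an exact 95% Poisson interval for those reads.

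Replicate numbers 3, 8 and 11 occur at every location, and the labels do not say what they mark. Deviations from the location means over the 5000 most variable genes were correlated between libraries. All 63 pairs of libraries with the same number had a correlation between 0.24 and 0.54 (median 0.42), while pairs with another number and location lay between -0.32 and -0.05 (median -0.21). Each of the 21 libraries correlated best with one of its own number. The numbers therefore pair the samples by this check of the data. The fit of record had no block, and the fit with the replicate block, which called 4084 genes between dorsal and ventral skin against 2409, is given beside the count of each comparison, and beside a list's count where it moved it by more than 1.5 times. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples, part of which may be technical.

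Alternatives changed one choice at a time, except that edgeR changed both the model and the scaling: pseudocounts of 0.5 and 8, quantile normalization, no filter, a fit of the compared libraries alone, a replicate block, leaving out each library and each replicate number, leaving the flank out of the dorsal-ventral comparison, camera with an estimated correlation, and counting models on the recovered reads, edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0. The replicate number as a random effect was added after the data had been seen. The fitting steps were tested on simulated data with 200 changed genes. For dorsal against ventral, limma recovered 31.3% of the genes changed 1.5-fold, 58.2% at 2-fold and 97% at 4-fold, with 6 false among 130 calls over 13832 genes. For dorsal anterior against dorsal posterior the shares were 3%, 22.4% and 68.2%, with 0 false among 62 calls over 13853 genes. In the simulated dorsal-ventral comparison edgeR made 127 calls with 5 false and DESeq2 180 with 43 false. The simulated libraries were drawn independently, with no effect shared by a replicate number. These shares and false calls may therefore not hold for the real libraries, where numbers matter and more genes were called. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.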

Results

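The series was collected to find molecules whose expression is restricted to presumptive colour domains in the skin of Estrildid finches. RNA was sequenced from the skin of zebra finch (Taeniopygia guttata, a songbird with sharply bounded plumage patches) embryos at stage HH28, an early stage at which feather fields are being laid out. There were 9 dorsal libraries, 3 each from anterior, saddle and posterior skin, and 12 ventral libraries, 3 each from anterior, ventral-most, flank and posterior skin. Dorsal libraries held 20.1 ± 2.5 M reads (mega, SD, n = 9) and ventral libraries 17.5 ± 2.0 M (SD, n = 12). The smallest library, ventral posterior replicate 8, held 12.9 M reads and the largest, dorsal posterior replicate 8, held 23.0 M. Levels are given as normalised read counts.

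The libraries separated first by body side. The first principal component held 17.1% of the variance, of which body side explained 90.3%. The second component held 14.9% and the third 12.3%, and the replicate number explained 95.3% and 80.3% of these. Location explained 82% of the fourth component, which held 9.1%. Across all 7 locations limma called 2152 of 14005 genes (4208 with the replicate block), of which 1872 differed at least 2-fold between the highest and the lowest location. Among the genes with the largest F were the transcription factors FOXB1, HOXC9, HAND2 and HOXA11. Their largest differences between location means were 7.86, 9.29, 8.96 and 10.64 on the log2 scale. The count was 3462 with DESeq2, and leaving out replicate number 3, 8 or 11 gave 973, 244 and 1223.

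**Figure D1:**
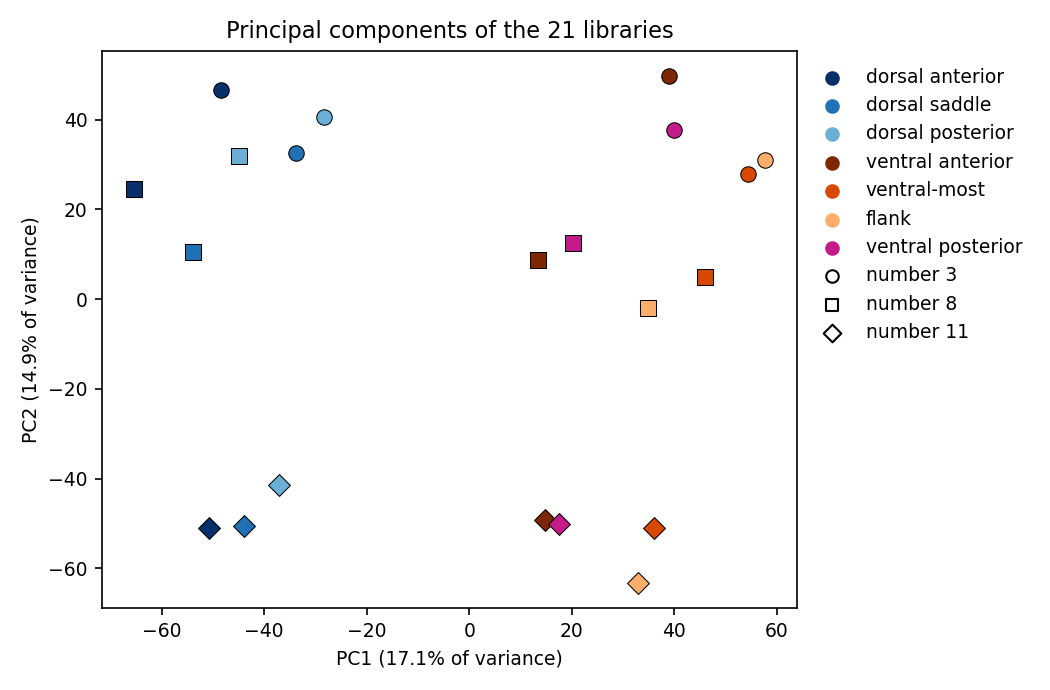
Each point is a library, placed by its scores on the first (x axis) and second (y axis) principal component of log2(normalised count + 1), with colour for the location and circle, square or diamond for replicate number 3, 8 or 11. The first component, 17.1% of the variance, parts dorsal from ventral libraries, and the second, 14.9%, parts the replicate numbers.

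Dorsal and ventral skin were compared to find genes that mark either side. The zinc finger gene ZIC1 (GSZG0013897, chromosome 9, 13479678 to 13483103), which marks dorsal somite derivatives, stood at 2772 ± 1806 dorsally and 98.9 ± 168 ventrally (SD, n = 9 and 12; log2 fold change 7.20, SE 0.55, adjusted p = 2.08e-07). On the ventral side, HAND2 (GSZG0010404, chromosome 4, 34428115 to 34429737), a lateral plate transcription factor, averaged 422 ± 228 against 1.56 ± 3.77 in dorsal skin (log2 fold change -7.91, SE 0.40, adjusted p = 7.42e-10). FGF10 (GSZG0017987, chromosome Z, 44571900 to 44628084), a mesenchymal growth factor of limb and skin, averaged 168 ± 94.5 ventrally and 8.50 ± 7.64 dorsally (log2 fold change -4.42, SE 0.31, adjusted p = 9.06e-08).

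Genes of pigment production were higher dorsally, and a secreted pigment regulator was higher ventrally. ASIP (GSZG0006812, chromosome 20, 1861698 to 1865428) encodes agouti signalling protein, an antagonist of the melanocortin receptor that shifts melanocytes away from black pigment. It averaged 5466 ± 4938 in ventral libraries (SD, n = 12) and 114 ± 176 in dorsal ones (SD, n = 9) (log2 fold change -6.06, SE 0.44, adjusted p = 1.12e-07). TYR (GSZG0000860, chromosome 1, 82001752 to 82044800), the rate-limiting enzyme of melanin synthesis, averaged 1431 ± 645 dorsally and 124 ± 141 ventrally (log2 fold change 5.57, SE 0.94, adjusted p = 0.000449). Of 18 tested genes of the melanocyte and melanin list, 14 were higher dorsally and 0 lower (16 and 0 adjusted over the list alone), with a median log2 fold change of 1.64. Among them were TYRP1 (4.83, SE 0.70) and SLC45A2 (4.37, SE 0.66), both of the melanosome, the receptor gene KIT (2.47, SE 0.30), on which melanoblasts depend, and SLC24A5 (0.73, SE 0.08). Camera placed the list above other genes (adjusted p = 2.12e-10), but with adjusted p = 0.0806 with an estimated correlation.

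EDNRB and MITF were among the 4 members of the melanocyte list that limma did not call. EDNRB (GSZG0000822), an endothelin receptor gene, had a log2 fold change of 0.81 (SE 0.29, adjusted p = 0.0642). It was called with the replicate block (adjusted p = 0.0187), edgeR (0.0449), DESeq2 (0.0155) and without the flank (0.0385). MITF (GSZG0002008), the master regulator of melanocytes, gave -0.22 (SE 0.16, adjusted p = 0.412). Of 13 secreted regulators of melanocytes, 1 was higher dorsally and 3 lower (2 and 5 adjusted over the list alone, 1 and 6 with the replicate block), with a median of -0.59 and a camera adjusted p of 0.136. KITLG (GSZG0004914, chromosome 1A, 42312985 to 42338833), the ligand of KIT, averaged 557 ± 222 dorsally and 265 ± 97.9 ventrally (log2 fold change 1.06, SE 0.21, adjusted p = 0.00178), and GDNF was lower dorsally (-2.21, SE 0.49). The calls of KITLG and GDNF ended without replicate number 8, and that of GDNF also without number 11.

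**Figure D2:**
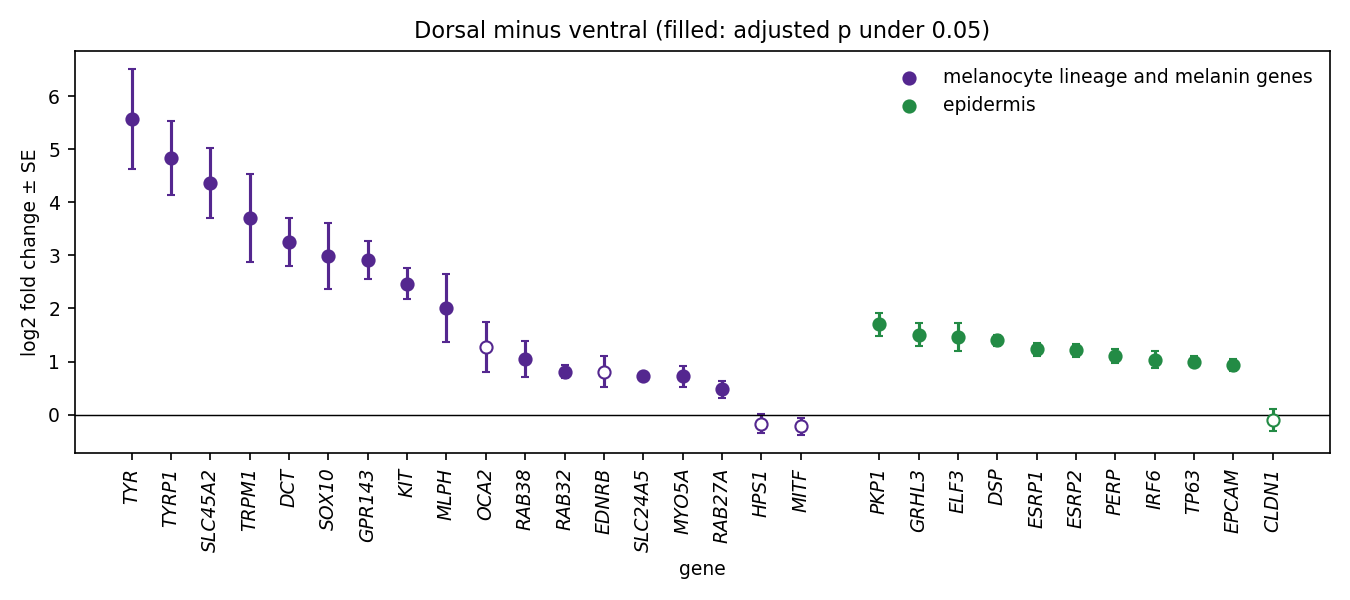
The y axis gives the dorsal minus ventral difference in mean log2(normalised count + 1) for 18 melanocyte and 11 epidermis genes (x axis), each a point with its SE, filled where the adjusted p was below 0.05. Of the melanocyte genes 14 were called and higher dorsally, led by TYR (5.57), and of the epidermis genes 10.

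Epidermal genes were also higher dorsally. Of 11 epidermis genes, 10 were higher dorsally and 0 lower (10 and 0 adjusted over the list alone), with a median log2 fold change of 1.21. They included the desmosome gene DSP (1.40, SE 0.11) and the epithelial splicing factors ESRP1 (1.23, SE 0.12) and ESRP2 (1.21, SE 0.13). Camera gave an adjusted p of 6.37e-13 (adjusted p = 0.0105 with an estimated correlation). Of 18 dermal fibroblast and matrix genes, 4 were higher and 3 lower (5 and 3 adjusted over the list alone), with a median of -0.01, a mean of 0.44 and a camera adjusted p of 0.473. COL12A1 was among the higher ones (2.78, SE 0.24). Of 23 feather placode and dermal condensation genes, 6 were higher and 4 lower (7 and 4 adjusted over the list alone). Their median was 0.18, their mean -0.07 and the camera direction upward (adjusted p = 0.296).

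Regulators of mesoderm went both ways. Of 13 lateral plate, ventral body wall and limb regulators, 7 were lower dorsally and 1 higher (7 and 2 adjusted over the list alone), with a median log2 fold change of -1.90 (camera adjusted p = 0.000215, and adjusted p = 0.0105 with an estimated correlation). They included HAND2, GATA5 (-6.22, SE 0.89) and ISL1 (-3.12, SE 0.51). Of 11 somite and dorsal dermis regulators, 4 were higher and 5 lower (5 and 5 adjusted over the list alone), with a median of 0.18, a mean of 1.40 and a camera adjusted p of 0.345. ZIC1 and DMRT2 (3.05, SE 0.50), a somite gene, were among the higher ones. DMRT2 was not higher than at every ventral location, since it averaged 12190 ± 5896 in ventral posterior skin against 5788 ± 4071 dorsally. Among HOX genes of paralog groups 1 to 5, 2 of 7 were higher (2 higher and 2 lower adjusted over the list alone; median 0.00, camera adjusted p = 0.273), in groups 6 to 8, 1 of 5 (1 and 0; 0.53, 0.303), and in groups 9 to 13, 2 of 7 (4 and 1; 1.26, also with 1 member at its bound, 0.151). HOXD3 (2.25, SE 0.18) and HOXD4 (2.43, SE 0.24) were the higher members of groups 1 to 5.

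Signalling genes were called in both directions within each pathway but the retinoic acid list. Of 25 WNT genes, 9 were higher dorsally and 5 lower (11 and 8 adjusted over the list alone; median 0.44, camera adjusted p = 0.151). WNT6, an ectodermal ligand, was higher (1.41, SE 0.16), as was the feedback inhibitor gene NKD1 (1.57, SE 0.16), and WNT5A, a mesenchymal ligand, was lower (-1.47, SE 0.14). Of 16 BMP genes, 5 were higher and 2 lower (7 and 2 adjusted over the list alone; 0.25, 0.051). The BMP antagonist genes GREM1 (2.94, SE 0.41) and TWSG1 (0.70, SE 0.12) were higher. Of 18 FGF genes, 1 was higher and 6 lower (2 and 6 adjusted over the list alone, 4 and 7 with the replicate block; -0.16, 0.215), FGF7 among the lower (-2.65, SE 0.40) and the receptor gene FGFR2 (0.88, SE 0.10) the higher one. Of 10 retinoic acid genes, 0 were higher and 2 lower (0 and 2 adjusted over the list alone; -0.55, 0.051). These were the synthesis enzyme gene ALDH1A1 (-5.65, SE 0.61) and CRABP1 (-1.64, SE 0.23), which encodes a binding protein. ALDH1A1 had 3 reads in all dorsal libraries and a ventral to dorsal ratio of 650 (95% counting interval 222 to 3150). CRABP1 was not lower than at every ventral location, since it averaged 975 ± 473 in ventral posterior skin against 2939 ± 2099 dorsally.

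Markers of other tissues were measured for what a piece of skin can carry along. Of 12 endothelial genes, 0 were higher dorsally and 4 lower (0 and 7 adjusted over the list alone, 1 and 6 with the replicate block), among them FLT1 (-1.32, SE 0.28) and ERG (-0.50, SE 0.10), with a median of -0.95 (camera adjusted p = 0.00498, and adjusted p = 0.445 with an estimated correlation). Of 22 cell cycle genes, 0 were higher and 2 lower (0 and 0 adjusted over the list alone, 0 and 8 with the replicate block; median -0.12), with a camera adjusted p of 0.051, or 0.0193 with the replicate block. The neuron list had 1 higher and 1 lower among 13 (1 and 1 adjusted over the list alone; -0.04, camera adjusted p = 0.734), the higher one SYT1 (0.73, SE 0.13) and the lower STMN2 (-4.57, SE 0.62). Of 5 spinal cord progenitor genes, 1 was higher (2 adjusted over the list alone and 2 with the replicate block; 0.78, 0.136), the transcription factor gene SOX21 (2.33, SE 0.21), which embryonic skin also expresses. Of 9 Schwann cell and neural crest genes, 3 were higher and 2 lower (4 and 3 adjusted over the list alone; 0.68, 0.273), TFAP2B (2.20, SE 0.16) and SOX10 (2.99, SE 0.62) among the higher. The calls of FLT1 and SOX10 ended without replicate number 8 and that of SYT1 without number 3.

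Limma called 0 of 16 skeletal muscle genes (0 adjusted over the list alone, 0 at an unadjusted p below 0.05, and 0 with edgeR and DESeq2; median 0.08, camera adjusted p = 0.771). It called 0 of 9 macrophage and leukocyte genes (0 adjusted over the list alone, 2 unadjusted, 0 with edgeR, 2 with DESeq2 and 3 with the replicate block; -0.52, 0.136). Of 11 cartilage genes, 5 were higher and 2 lower (5 and 4 adjusted over the list alone; 0.84, 0.345), SOX6 among the higher (1.28, SE 0.20). Of 8 erythroid genes, 1 was lower (5 adjusted over the list alone and 2 with the replicate block; -0.70, 0.051). Of 6 liver genes, 2 were higher (2 adjusted over the list alone; 0.24, 0.136), the plasma protein genes APOH (3.56, SE 0.53) and ITIH2 (3.71, SE 0.63). Of 9 heart genes, 1 was higher and 1 lower (2 and 1 adjusted over the list alone; 1.13, 0.594). Of 6 mesothelium and kidney genes, 1 was higher and 3 lower (1 and 3 adjusted over the list alone; -0.43, 0.273), UPK1B the higher (1.69, SE 0.24) and BNC2 among the lower (-1.12, SE 0.15). Of 7 smooth muscle and pericyte genes, 1 was higher (1 adjusted over the list alone), MYLK (0.97, SE 0.21), with a median of 0.04, a mean of -0.09 and the camera direction upward (adjusted p = 0.734). Of 17 immediate early and stress genes, 1 was higher (1 adjusted over the list alone, 2 higher and 1 lower with the replicate block; 0.20, 0.303), HSPA2 (0.61, SE 0.11). Of 15 hypoxia and glycolysis genes, 1 was higher (1 adjusted over the list alone, 1 higher and 2 lower with the replicate block), P4HA1 (0.48, SE 0.09), with a median of 0.02, a mean of -0.02 and the camera direction upward (0.823). MYLK and HSPA2 were not called without replicate number 3, nor HSPA2 without number 8.

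In all, limma called 2409 of 14005 genes between dorsal and ventral skin, 1304 higher dorsally and 1105 lower. Of these, 597 were at least 2-fold higher and 439 at least 2-fold lower, and 916 of the called genes had no symbol. With the replicate block the count was 4084 (2137 higher and 1947 lower). It was 1525 and 813 without replicate numbers 3 and 8. Other genes with large differences were FOXB1, with 3 ventral reads and a ratio of 847 (95% counting interval 290 to 4110), the EYA family gene EYA4 (log2 fold change -3.76) and the homeobox gene LHX8 (-3.97).

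**Figure D3:**
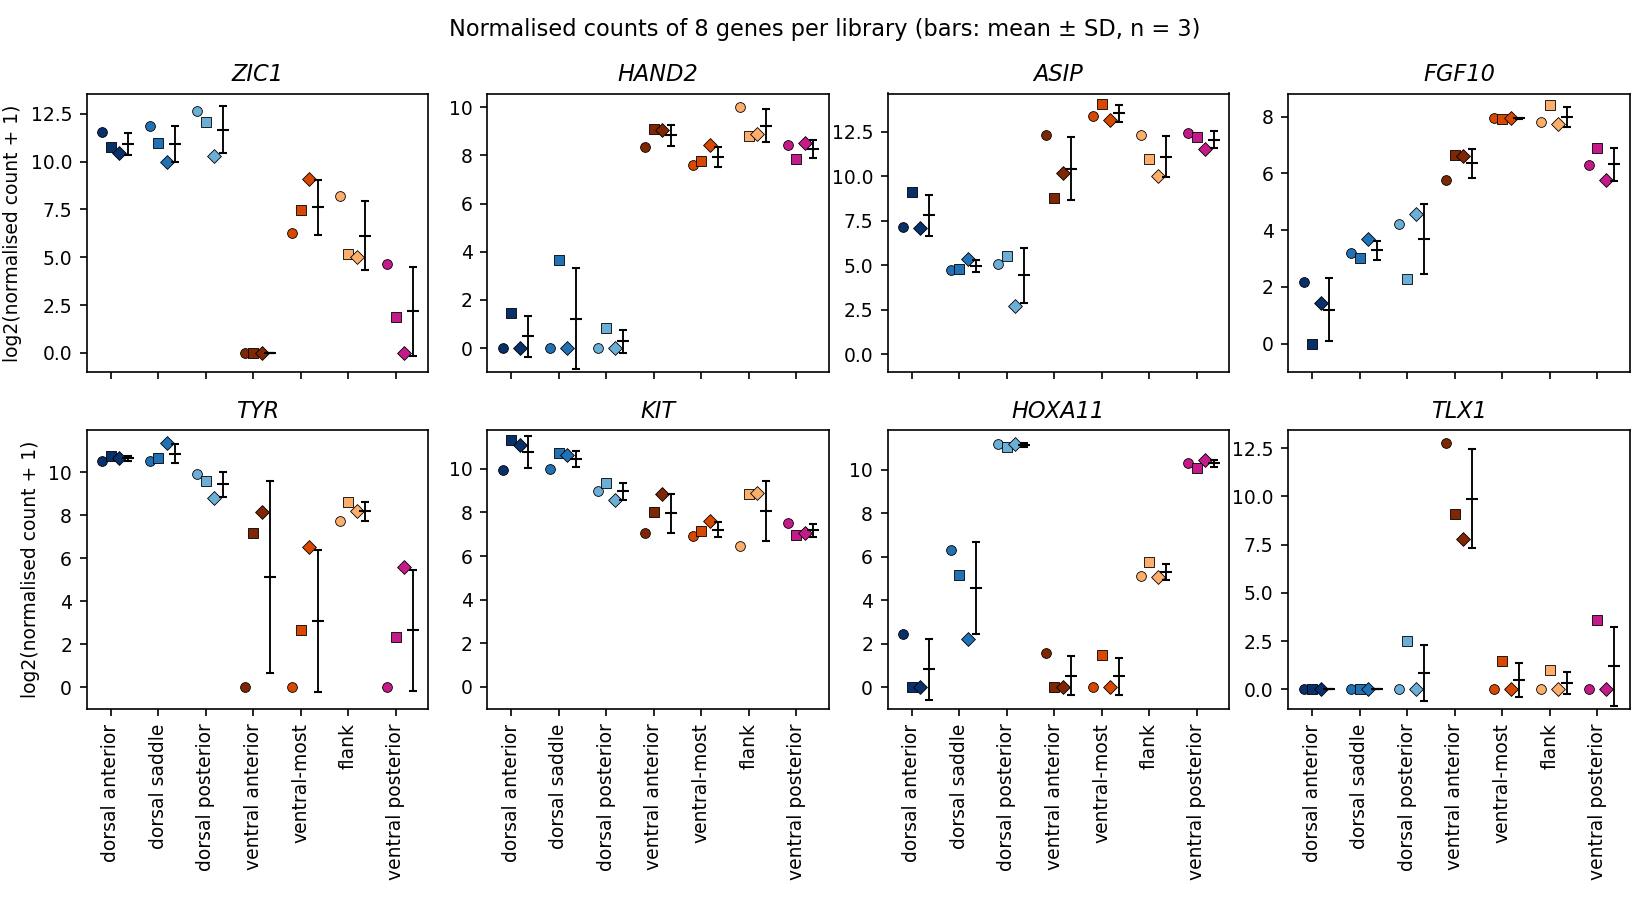
Each panel gives log2(normalised count + 1) of a gene (y axis) per library at the 7 locations (x axis), with circle, square and diamond for replicate numbers 3, 8 and 11 and a bar for the mean ± SD of 3 libraries. ZIC1, TYR and KIT were higher dorsally, HAND2, ASIP and FGF10 ventrally, HOXA11 had its highest means in posterior skin of both sides, and TLX1 in ventral anterior skin.

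Dorsal anterior and dorsal posterior skin were compared to find genes graded along the back. HOXA11 (GSZG0006122, chromosome 2, 52641989 to 52644396), a posterior HOX gene, averaged 1.46 anteriorly and 2259 ± 144 posteriorly (SD, n = 3; log2 fold change -10.33, SE 0.84, adjusted p = 4.74e-06). HOXD11 (GSZG0012872, chromosome 7, 17038300 to 17039721) had 0 reads in the anterior libraries and 534 ± 338 posteriorly, at least 615-fold lower anteriorly. In the other direction, HOXA4 (GSZG0006117, chromosome 2, 52583050 to 52584502) averaged 651 ± 421 anteriorly and 19.0 ± 9.35 posteriorly (log2 fold change 4.89, SE 0.53, adjusted p = 7.87e-05). SLC18A2 (GSZG0012458, chromosome 6, 29304080 to 29329677), a vesicular monoamine transporter gene, averaged 571 ± 294 anteriorly, 165 ± 26.3 in the saddle and 5.89 ± 8.26 posteriorly (log2 fold change 7.10, SE 0.90, adjusted p = 0.000248). The calcium channel subunit gene CACNG3 (GSZG0002861) was lower anteriorly (-7.56, SE 0.78), as was the estrogen receptor gene ESR1 (GSZG0009487; -5.80, SE 0.84), while the T-box gene TBX18 (GSZG0009656; 3.93, SE 0.52) and the homeobox gene EMX2 (GSZG0012460; 3.94, SE 0.63) were higher. Leaving out replicate number 8 ended the calls of SLC18A2, ESR1, TBX18 and EMX2, and leaving out number 3 that of ESR1.

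HOX genes changed in groups. In paralog groups 1 to 5, 4 of 7 genes were higher in dorsal anterior skin and 0 lower (5 and 0 adjusted over the list alone), with a median log2 fold change of 1.44. Camera gave an adjusted p of 3.33e-13 (adjusted p = 0.00421 with an estimated correlation), and HOXA2 (3.46, SE 0.35) and HOXA3 (1.44, SE 0.18) were among them, the latter not called without replicate number 8. In groups 9 to 13, 6 of 7 were lower and 0 higher (7 and 0 adjusted over the list alone), with a median of -6.20, which stayed at -6.20 with the 2 members without anterior reads, HOXD11 among them, at their bound. Camera gave 2.15e-21 (adjusted p = 1.99e-05 with an estimated correlation), and HOXC9 was among the lower ones (-7.68, SE 0.66). In groups 6 to 8, limma called 0 of 5 (0 adjusted over the list alone, 0 unadjusted, and 0 with edgeR and DESeq2; median -0.04, camera adjusted p = 0.768).

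In the melanocyte list 1 of 18 genes was higher anteriorly (3 higher and 1 lower adjusted over the list alone, 3 higher with the replicate block; median 0.80), SLC24A5, a cation exchanger gene of the melanosome (1.20, SE 0.15, adjusted p = 0.000171; not called without replicate number 8). Camera gave 0.01 for the list (adjusted p = 0.698 with an estimated correlation). ASIP was higher in dorsal anterior skin, with 282 ± 244 against 27.8 ± 20.2 (SD, n = 3; log2 fold change 3.38, SE 0.82, adjusted p = 0.0372). That call was lost with edgeR, in a fit of the compared libraries alone, without any 1 of the 3 replicate numbers, and without dorsal anterior replicate 3 (3.69) or 8 (2.72) or dorsal posterior replicate 3 (3.71) or 11 (2.51). KIT (1.81, SE 0.55, adjusted p = 0.109) and KITLG (1.01, SE 0.39, adjusted p = 0.272) were called with the replicate block (adjusted p = 0.0256 and 0.00643), KIT also with DESeq2 (0.00729) and without replicate number 3 (0.0193), and neither MITF (0.50, SE 0.30) nor EDNRB (-1.45, SE 0.54) was called.

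Of the epidermis list 1 gene was higher anteriorly (5 adjusted over the list alone and 2 with the replicate block; median 0.63), with a camera adjusted p of 2.95e-06 (adjusted p = 0.116 with an estimated correlation). Of the WNT list 3 genes were higher (3 higher and 1 lower adjusted over the list alone; median 0.44), with a camera adjusted p of 0.0295 (adjusted p = 0.496 with an estimated correlation). WNT2 was among them (2.44, SE 0.45), a call that ended in a fit of the compared libraries alone and without any 1 of the 3 replicate numbers. Camera placed the skeletal muscle, erythroid and endothelial lists below other genes, each losing the call with an estimated correlation. The skeletal muscle list had a median of -1.49 with 0 genes called by limma (0 adjusted over the list alone, 0 unadjusted, and 0 with edgeR and DESeq2; camera adjusted p = 0.0312, 0.0733 with the replicate block, and adjusted p = 0.89 with an estimated correlation). The erythroid list had a median of -0.94 with 1 gene lower, LMO2 (-2.28, SE 0.36; not called without replicate number 3 or 8), and 1 adjusted over the list alone (camera adjusted p = 0.018, and adjusted p = 0.499 with an estimated correlation). The endothelial list had a median of -0.66 with 0 genes called by limma (0 adjusted over the list alone, 3 unadjusted, 0 with edgeR, 2 with DESeq2 and 1 with the replicate block; camera adjusted p = 0.0228, and adjusted p = 0.766 with an estimated correlation). The macrophage list passed with the replicate block (camera adjusted p = 0.0402 against 0.0509).

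Limma called 318 genes between dorsal anterior and dorsal posterior skin, 106 higher anteriorly and 212 lower (79 and 187 at least 2-fold), and 740 with the replicate block (280 and 460). DESeq2 called 598, a fit of the compared libraries alone 128, and the count was 188 without dorsal anterior replicate 3, 207 without dorsal anterior replicate 8, 165 without dorsal posterior replicate 3 and 175 without dorsal posterior replicate 11. Without replicate numbers 3, 8 and 11 it was 70, 26 and 175.

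Ventral anterior and ventral posterior skin were compared in the same way. The homeobox gene TLX1 (GSZG0012406, chromosome 6, 22442858 to 22448863) averaged 2552 ± 3756 in ventral anterior skin, from 222 to 6885 between libraries, and 3.65 ± 6.32 in ventral posterior skin (SD, n = 3; log2 fold change 8.69, SE 1.15, adjusted p = 0.000459). A fit of the compared libraries alone and DESeq2 did not call it. CRABP1 (GSZG0001284, chromosome 10, 503916 to 517304), which binds retinoic acid in the cytoplasm, averaged 35950 ± 6612 anteriorly and 975 ± 473 posteriorly (log2 fold change 5.34, SE 0.42, adjusted p = 1.56e-06). The homeobox gene DLX1 (GSZG0012859) was also higher anteriorly (7.49, SE 1.08, adjusted p = 0.00107). DMRT2 (GSZG0018111, chromosome Z, 65305794 to 65308811), a somite transcription factor gene, averaged 358 ± 421 anteriorly and 12190 ± 5896 posteriorly (log2 fold change -5.98, SE 0.92, adjusted p = 0.002). The matrix gene COL14A1 was lower anteriorly (-2.19, SE 0.19), while DCN, which encodes the proteoglycan decorin, was higher (0.65, SE 0.12). A fit of the compared libraries alone ended the calls of DMRT2 and DCN, as did leaving out replicate number 8, and for DCN number 3 or 11.

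All 5 tested HOX genes of paralog groups 6 to 8 were lower in ventral anterior skin (5 adjusted over the list alone), with a median log2 fold change of -3.37, unchanged at -3.37 with HOXC6 at its bound (camera adjusted p = 2.51e-16, and adjusted p = 4.38e-05 with an estimated correlation). HOXC6 had 0 anterior reads and was at least 15.2-fold lower there, and HOXB7 (GSZG0008386, chromosome 27, 4511442 to 4517300) had 2 reads and a posterior to anterior ratio of 119 (95% counting interval 32.9 to 980). In groups 9 to 13, 5 of 7 were lower and 0 higher (5 and 0 adjusted over the list alone; median -6.31, also with 1 member at its bound, camera adjusted p = 4.64e-16, and adjusted p = 5.91e-05 with an estimated correlation). HOXA11 had 2 anterior reads against 1262 ± 152 posteriorly, a ratio of 1910 (95% counting interval 530 to 15800), and HOXA9 (GSZG0005534) averaged 2.27 against 819 ± 111 (-8.05, SE 0.66). In groups 1 to 5, 3 of 7 were higher and 0 lower (3 and 2 adjusted over the list alone), HOXA3 (2.31, SE 0.18) and HOXA2 (2.84, SE 0.35) among them. The calls of HOXA2 and HOXC6 ended without replicate number 8, and that of HOXC6 in a fit of the compared libraries alone. The median was -0.23, the mean 0.36 and the camera direction upward (adjusted p = 0.0371, 0.148 with the replicate block, and adjusted p = 0.404 with an estimated correlation).

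Of 10 retinoic acid genes, 2 were higher in ventral anterior skin (2 higher and 1 lower adjusted over the list alone; median 0.89, camera adjusted p = 0.00595, and adjusted p = 0.0726 with an estimated correlation). These were CRABP1 and the synthesis enzyme gene ALDH1A2 (4.11, SE 0.75), whose call ended in a fit of the compared libraries alone and without replicate number 8 or 11. The lateral plate list had 1 gene higher and 1 lower (1 and 4 adjusted over the list alone; median -1.72, camera adjusted p = 0.0204, and adjusted p = 0.0726 with an estimated correlation). Limma called 0 melanocyte genes (0 adjusted over the list alone, 5 unadjusted, 0 with edgeR and DESeq2, and 2 with the replicate block), with a median of 0.82 (camera adjusted p = 0.00745, and adjusted p = 0.417 with an estimated correlation). ASIP (-1.63, SE 0.82, adjusted p = 0.51), KIT (0.78, SE 0.55), KITLG (-0.19, SE 0.39) and EDNRB (-0.13, SE 0.54) were not called, and MITF (0.85, SE 0.30, adjusted p = 0.22) was called with the replicate block (adjusted p = 0.0395).

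Muscle lists stood above other genes by camera, each losing the call with an estimated correlation. The skeletal muscle list had a median of 2.03 with 0 genes called by limma (0 adjusted over the list alone, 3 unadjusted, and 0 with edgeR and DESeq2; camera adjusted p = 6.05e-05, and adjusted p = 0.417 with an estimated correlation). The heart list, which shares sarcomere genes, had a median of 1.94 with 0 called by limma (0 adjusted over the list alone, 3 unadjusted, and 0 with edgeR and DESeq2; camera adjusted p = 0.0371, 0.0839 with the replicate block, and adjusted p = 0.417 with an estimated correlation). The smooth muscle list had 1 gene higher (1 adjusted over the list alone; median 0.89, camera adjusted p = 0.0122, and adjusted p = 0.217 with an estimated correlation). The erythroid list had a median of -0.98 with 0 called by limma (0 adjusted over the list alone, 1 unadjusted, and 0 with edgeR and DESeq2; camera adjusted p = 0.0371, 0.0839 with the replicate block, and adjusted p = 0.404 with an estimated correlation).

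Limma called 246 genes between ventral anterior and ventral posterior skin, 129 higher anteriorly and 117 lower (115 and 105 at least 2-fold), and 589 with the replicate block (314 and 275). DESeq2 called 499. The balance turned in a fit of the compared libraries alone, with 41 calls (17 higher and 24 lower), and without ventral anterior replicate 8 (135, 56 and 79) or 11 (141, 61 and 80), ventral posterior replicate 3 (136, 61 and 75), or replicate number 8 (27, 10 and 17) or 11 (94, 39 and 55).

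**Figure D4:**
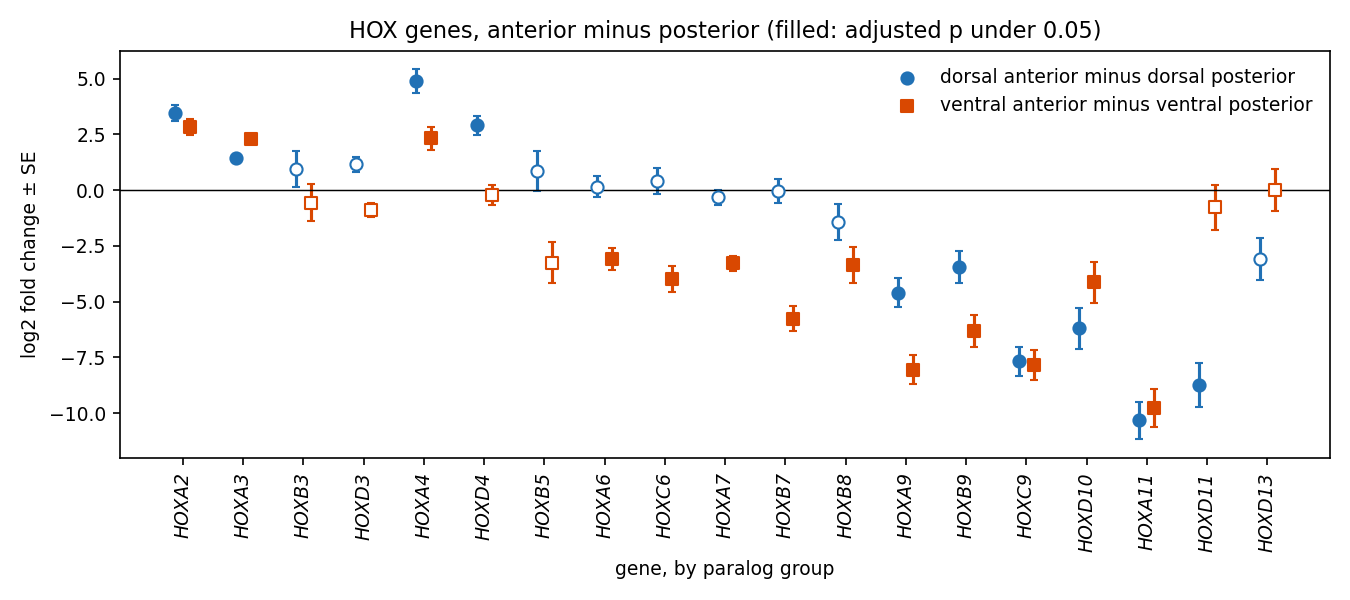
The y axis gives the anterior minus posterior difference in mean log2(normalised count + 1), with its SE, for 19 HOX genes (x axis) on the dorsal side (blue circles) and on the ventral side (orange squares), filled where the adjusted p was below 0.05. In paralog groups 9 to 13, 6 of 7 genes were lower anteriorly on the dorsal side (median -6.20) and 5 of 7 on the ventral side (-6.31), while groups 6 to 8 had medians of -0.04 dorsally and -3.37 ventrally.

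The anterior-posterior contrasts of the sides were then compared with each other by a test of their difference. HOXB7 differed by 5.73 (SE 0.77, adjusted p = 0.00736): its contrast was -0.04 dorsally and -5.76 ventrally. SLC18A2 differed by 8.53 (SE 1.28, adjusted p = 0.00736), with 7.10 dorsally and -1.43 ventrally, and CACNG3 by -7.40 (SE 1.11, adjusted p = 0.00736), with -7.56 dorsally and -0.17 ventrally. Of the 5 HOX genes in groups 6 to 8, 4 had a more positive contrast dorsally and 0 a more negative one (4 and 0 adjusted over the list alone; median 3.24). The same held for 2 of 7 genes of groups 1 to 5 (4 and 1 adjusted over the list alone, 4 and 0 with the replicate block; median 2.05). Limma called 116 genes, 49 more positive dorsally and 67 more negative, and 411 with the replicate block (186 and 225).

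DESeq2 called 380 genes for this difference, and a fit of the compared libraries alone 34. The count was 65 without dorsal anterior replicate 3, 60 without dorsal anterior replicate 8, 56 without dorsal posterior replicate 3, 65 without dorsal posterior replicate 8, 74 without ventral anterior replicate 8, 66 without ventral posterior replicate 3 and 72 without ventral posterior replicate 8. Without ventral anterior replicate 11 it was 79, and the balance turned to 40 and 39. Leaving out replicate number 11 gave 37, and limma called 0 without number 3 or number 8, where 1194 and 793 genes had an unadjusted p below 0.05. With all libraries edgeR called 100.

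Each dorsal location was set against the mean of the others on its side. In dorsal anterior skin, SYNDIG1 (GSZG0009234), a synapse gene, averaged 315 ± 97.8 against 23.0 in the saddle and 31.6 posteriorly (log2 fold change 3.61, SE 0.55, adjusted p = 0.00138), and HOXC9 was lower (-8.16, SE 0.57). Of the HOX genes, 5 of 7 in groups 1 to 5 were higher (5 adjusted over the list alone; median 1.22) and 6 of 7 in groups 9 to 13 lower (7 adjusted over the list alone; -5.04, or -5.48 with the 2 members without anterior reads at their bound). Of 25 WNT genes 3 were higher (4 adjusted over the list alone). Limma called 287 genes (83 higher and 204 lower), and 610 with the replicate block. The count was 518 with DESeq2, 142 in a fit of the compared libraries alone, 139 without dorsal anterior replicate 3, 152 without dorsal anterior replicate 8, and 50 and 29 without replicate numbers 3 and 8, the latter of which ended the call of SYNDIG1.

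In the dorsal saddle, HOXC9 (GSZG0017367, unplaced sequence, 4895043 to 4897702) averaged 697 ± 30.8, against 1.47 ± 2.55 in dorsal anterior and 362 ± 44.9 in dorsal posterior skin (SD, n = 3; log2 fold change 4.79, SE 0.57, adjusted p = 0.00177). Leaving out replicate number 3, 8 or 11 ended that call, with log2 fold changes of 4.59, 5.21 and 4.57. Of the HOX genes in groups 9 to 13, 3 of 7 were higher (3 higher and 1 lower adjusted over the list alone; median 1.66). Limma called 20 genes (13 higher and 7 lower), 57 with the replicate block and 93 with DESeq2, while edgeR called 14, 12 of them higher and 2 lower. Without the filter the count was 11, and in a fit of the compared libraries alone 15 (7 higher and 8 lower). It was 4 without dorsal anterior replicate 3, 13 without dorsal anterior replicate 8, 2 without dorsal saddle replicate 3, 8 or 11, 3 without dorsal posterior replicate 3, 4 without dorsal posterior replicate 8 and 10 without dorsal posterior replicate 11. Leaving out replicate number 11 gave 4, and limma called 0 without number 3 or number 8, where 584 and 338 genes had an unadjusted p below 0.05.

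In dorsal posterior skin, HOXA11 (log2 fold change 8.46, SE 0.72, adjusted p = 1.54e-05) and HOXD11 (8.07, SE 0.86) were higher and SLC18A2 (-6.27, SE 0.78), EMX2 (-4.0, SE 0.55) and B3GALT2 (-3.39, SE 0.53) lower than in the other dorsal locations. HOX genes of groups 9 to 13 were higher in 4 of 7 cases (6 adjusted over the list alone; median 3.37) and those of groups 1 to 5 lower in 3 of 7 (4 adjusted over the list alone; -1.01). In the melanocyte list 1 gene, SLC24A5, was lower (3 adjusted over the list alone and 2 with the replicate block; median -0.78). The skeletal muscle list had a median of 2.52 there, with 0 genes called by limma (0 adjusted over the list alone, 4 unadjusted, and 0 with edgeR and DESeq2). Limma called 121 genes (73 higher and 48 lower), 475 with the replicate block, 379 with DESeq2 and 69 in a fit of the compared libraries alone, where the balance turned (33 higher and 36 lower). The count was 76 without dorsal anterior replicate 8, 74 without dorsal saddle replicate 8, 36 without dorsal posterior replicate 3, 49 without dorsal posterior replicate 8 and 39 without dorsal posterior replicate 11, and 8, 3 and 29 without replicate numbers 3, 8 and 11. It also turned without dorsal posterior replicate 3 (17 and 19) or 11 (16 and 23) and without number 3 (2 and 6). Leaving out a number ended the calls of HOXD11 (3), SLC18A2 and B3GALT2 (3 or 8) and EMX2 (8 or 11).

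Ventral-most skin was set against the other ventral locations. HOXB7 averaged 555 ± 130 there (SD, n = 3; log2 fold change 4.04, SE 0.45, adjusted p = 0.000367), and EMX2 was lower (-3.54, SE 0.52). HOXA11 had 2 reads, a ratio of other ventral to ventral-most skin of 639 (95% counting interval 177 to 5270) that edgeR did not call. That ratio rests mostly on ventral posterior skin, where HOXA11 averaged 1260, since ventral anterior skin also had only 2 reads. Of the 5 HOX genes in groups 6 to 8, 3 were higher (4 adjusted over the list alone and 4 with the replicate block; median 2.13). ASIP averaged 12470 ± 4428 in ventral-most skin, the highest of the 7 location means, but was not called against the other ventral locations (2.34, SE 0.67, adjusted p = 0.136). The epidermis list had 1 gene lower (7 adjusted over the list alone and 3 with the replicate block; median -0.54), and the skeletal muscle list a median of -2.86 with 0 called by limma (5 lower adjusted over the list alone, 7 unadjusted, 0 with edgeR and 4 with DESeq2). Limma called 95 genes (40 higher and 55 lower) and 339 with the replicate block, while edgeR called 87 (53 higher and 34 lower), DESeq2 316 and a fit of the compared libraries alone 35. The count was 21 without ventral-most replicate 3, 13 without replicate 8 and 44 without replicate 11, and 5 and 39 without replicate numbers 3 and 11. The balance turned without ventral-most replicate 3 (12 higher and 9 lower), ventral anterior replicate 8 (34 and 33), ventral posterior replicate 11 (41 and 39) or number 3 (5, all higher). Limma called 0 without number 8, where 683 genes had an unadjusted p below 0.05. The calls of HOXB7, EMX2 and HOXA11 ended without number 3 or 8, and that of EMX2 without 11.

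In flank skin, HOXD11 averaged 154 ± 88.3 (log2 fold change 6.66, SE 0.81, adjusted p = 0.000208). TMEM255B (GSZG0000601) was also higher (5.30, SE 0.90), and the matrix gene TGFBI (GSZG0002324), at 97.9 ± 6.01 against 20570 ± 11570 in ventral anterior skin, was lower (-5.35, SE 0.62), as were MAB21L2 (GSZG0010257; -7.09, SE 0.72) and the serotonin receptor gene HTR7 (GSZG0012358; -6.43, SE 0.65). Of 10 retinoic acid genes, 5 were higher (7 adjusted over the list alone; median 1.01), and HOX genes were higher in 2 of 5 (4 adjusted over the list alone) for groups 6 to 8. Limma called 427 genes (226 higher and 201 lower) and 1021 with the replicate block, edgeR 414 (275 and 139), DESeq2 774 and a fit of the compared libraries alone 228. The count was 188 without flank replicate 3, 165 without flank replicate 8, and 102 and 17 without replicate numbers 3 and 8. The balance turned without flank replicate 8 (77 higher and 88 lower) or 11 (153 and 236) and without number 11 (188 and 194). Leaving out number 8 ended the calls of TMEM255B and TGFBI, and number 3 that of TMEM255B.

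In ventral anterior skin, TLX1 was higher than in the other ventral locations (log2 fold change 9.21, SE 0.94, adjusted p = 2.36e-05), as were APCDD1L (GSZG0006937), which belongs to a family of WNT inhibitors, at 6999 ± 6309 (7.29, SE 1.18), SALL1 (6.63, SE 1.06) and the neurofilament gene NEFM (6.31, SE 0.81). All 5 HOX genes of groups 6 to 8 were lower (5 adjusted over the list alone; median -4.46, also with 1 member at its bound) and 5 of 7 in groups 9 to 13 (6 adjusted over the list alone; -4.49, or -4.84 with 1 member at its bound). HOXB7 had 2 reads there, a ratio of 501 (95% counting interval 139 to 4140). Of the skeletal muscle list 1 gene was higher (8 adjusted over the list alone; median 2.75), and of the heart list 1 (3 adjusted over the list alone; 2.36). Limma called 420 genes (221 higher and 199 lower) and 884 with the replicate block (436 and 448), edgeR 428 (297 and 131), DESeq2 751 and a fit of the compared libraries alone 257. The count was 220 without ventral anterior replicate 8, 210 without ventral anterior replicate 11, and 34 and 172 without replicate numbers 8 and 11. In these the balance turned, to 103 higher and 117 lower, 95 and 115, 13 and 21, and 84 and 88, as it did without ventral posterior replicate 3 (183 and 186). Leaving out number 8 ended the calls of APCDD1L, SALL1 and NEFM, and number 11 that of APCDD1L.

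In ventral posterior skin, the hindlimb homeobox gene PITX1 (GSZG0002504, chromosome 13, 9772760 to 9779174) averaged 2004 ± 126 (SD, n = 3; log2 fold change 6.74, SE 1.03, adjusted p = 0.00226), and HOXA11 (8.19, SE 0.68) and DMRT2 (5.86, SE 0.75) were also higher than in the other ventral locations, while CRABP1 was lower (-4.08, SE 0.35). HOX genes of groups 9 to 13 were higher in 4 of 7 cases (4 adjusted over the list alone; median 2.55), retinoic acid genes lower in 3 of 10 (3 adjusted over the list alone; -0.44), and lateral plate genes higher in 2 and lower in 1 of 13 (3 and 1 adjusted over the list alone; 1.10). Limma called 154 genes (81 higher and 73 lower) and 478 with the replicate block (222 and 256), edgeR 146 (109 and 37), DESeq2 403 and a fit of the compared libraries alone 86. The count was 67 without ventral posterior replicate 3, 63 without ventral posterior replicate 8, and 66, 6 and 69 without replicate numbers 3, 8 and 11, where number 8 ended the calls of PITX1 and DMRT2. The balance also turned without ventral anterior replicate 3 (109 higher and 117 lower) or flank replicate 3 (84 and 87), and with the replicate number as a random effect (485, 225 and 260).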

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

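The tests of epidermal share, read depth and spinal cord tissue in this part were chosen only after the results they bear on had been seen; the count of other splits and the test of chromosome Z were chosen before.

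A set of 116 genes stood out because their anterior-posterior contrast differed between dorsal and ventral skin by a test of the difference itself. The number of splits of the libraries with as many genes, the real one included, was 3 of 100, and 2 of 32 within replicate numbers. Because the numbers pair the samples, the latter share counts, and by it chance is not excluded at 0.05 for this set. Within numbers, the split as large besides the real one exchanged whole locations, with 405 genes. It carries the anterior-posterior differences of both sides and is no random mixing of libraries. Splits within numbers that mixed libraries of different locations called at most 46 genes. Of the HOX genes, 7 were called, among them HOXB7 (difference 5.73, SE 0.77), HOXA7 (2.96, SE 0.48), HOXC6 (4.36, SE 0.82) and HOXD11 (-7.96, SE 1.41). The others were HOXD4 (3.13), HOXA6 (3.24) and HOXD3 (2.05), added after their values had been seen. HOXA7, for example, had a contrast of -0.32 dorsally and -3.28 ventrally, and HOXD11 of -8.74 and -0.78. Ventral HOXD11 lay mostly in the flank (154 ± 88.3, against 39.1 ± 79.1 over all ventral libraries), and TLX1 averaged 0.523 ± 1.57 dorsally. The small contrasts of these genes on those sides rest on values near 0. SLC18A2 (8.53), EMX2 (4.24), TBX18 (4.44), SLC24A5 (1.32) and CASR (5.87) had the more positive contrast dorsally. CACNG3 (-7.40), CRABP1 (-3.74), TLX1 (-9.53), ALX1 (-5.85), RERGL (-7.74) and NTRK3 (-7.73) had the more positive contrast ventrally. The skin genes COL14A1 (1.63) and DSP (1.68, with 0.84 dorsally and -0.83 ventrally) also differed. Among the genes given here, adjusted p ran from 0.00736 for HOXB7 to 0.0438 for HOXD3. Groups of 3 libraries were not tested for outlying samples.

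Genes of melanin production and of the epidermis were higher in dorsal than in ventral skin, and a larger share of epidermis in the dorsal pieces is a candidate explanation, since melanoblasts enter the epidermis. Cells that come with the epidermis would rise no more than the epidermis score, the mean of its list, which was 1.13. The 14 called melanocyte genes exceeded it by a median of 1.56 (1.42 to 1.68 leaving out a library). They were chosen by their call in this same comparison, however. Over all 18 tested members the median change was 1.64, so that excess decides nothing for the list. Of the 14, 8 exceeded the 1.70 of PKP1, the highest epidermis gene, by more than 2 SE. This argues against this share as the whole cause for those 8, if melanocyte transcripts rise no more than epidermal ones. The 8 were picked by these same values, and the SE of PKP1 was not counted. For 6 of the 14, RAB38, RAB27A, MYO5A, SLC24A5, RAB32 and MLPH, the change was not above that of the epidermis score by more than 2 SE, so a larger share of epidermis in the dorsal pieces cannot be told apart from a change in melanocytes for those. Fewer reads in the ventral libraries were not needed for the pattern: after all libraries were thinned to 12.9 M reads the median was still 2.69 and 13 of the 14 genes were called. Values are divided by size factors, so thinning changes their noise more than their means, and this median could hardly have moved. A difference in melanocytes between the sides stays open and untested, and MITF, the master regulator in the same list, was not called (-0.22, SE 0.16).

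FOXB1, ZIC1, SOX21 and PAX3 (3.04, SE 0.51), all known from the neural tube as well as from dorsal mesoderm or skin, were higher dorsally with a median of 5.12, and spinal cord tissue in the dorsal pieces might bring such transcripts. Spinal cord would also bring neuron genes, and these had a median of -0.04 (quartiles -0.33 to 0.44). STMN2 averaged 10.2 dorsally and 690 ventrally, GAP43 67.7 and 116, NEFM 10.7 and 80.3, CRMP1 1220 and 1420, and ELAVL4 435 on each side. SYT1, the 1 neuron gene called higher, averaged 427 and 258 (0.73, SE 0.13). The highest in the list was SCG2 (0.75, SE 0.54, not called), far below the 5.12. Ventral pieces also held neuron transcripts, unevenly: STMN2 ran from 0 to 3359 and NEFM from 0 to 425.8 between ventral libraries. A dorsal-ventral difference near 0 in neuron genes therefore cannot exclude spinal cord in the dorsal pieces, which stays open. Dorsal libraries held at most 18.81 of STMN2 and 24.74 of NEFM. The 4 other tested spinal cord progenitor genes had a median of 0.45, the lowest limma adjusted p being LMX1A's (1.56, 0.0880, and 0.0471 adjusted over the list alone), and PAX3 was added to this set after its value had been seen.

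Libraries separated by replicate number on the second and the third principal component, and 6676 genes differed between numbers. Embryos of different sex behind the numbers could produce this. The largest difference between numbers in the median of 526 chromosome Z genes relative to 9476 genes on other chromosomes was 0.04 on the log2 scale (bootstrap 0.009 to 0.085), and 40.2% of tested Z genes differed between numbers against 48% of the others, which argues against sex as the cause of the separation by replicate number, embryos of different sex behind the replicate numbers, unless each number pools both sexes. Litter, day and library batch are not in the labels and stay open and untested.

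The number of splits of the libraries with as many genes called as the real one, the real one included, was 1 of 100 for any difference among locations (real 2152, highest other 319), and 1 of 100 for dorsal against ventral (2409, highest other 53), dorsal anterior (287, 218), the flank (427, 201) and ventral anterior (420, 50), each against the other locations of its side. A chance assignment of single libraries can be excluded at 0.05 for these, and splits within replicate numbers gave the same answer. No split for dorsal against ventral, the flank or ventral anterior skin exchanged whole locations. Those splits show that libraries of a location are alike, and whether other groupings of intact locations call as many genes was not tested. It was 2 of 100 for ventral-most skin (95, 298), 3 of 100 for ventral posterior skin (154, 237), 4 of 98 for the dorsal saddle (20, 250) and 4 of 96 for dorsal posterior skin (121, 287). Within replicate numbers 5 of 71 splits for the saddle, 4 of 71 for dorsal posterior skin and 5 of 100 for ventral-most skin were as large, so chance is not excluded for these counts there, while 2 of 99 were for ventral posterior skin. The highest other split exchanged whole locations for the difference between the contrasts (405 genes) and for dorsal posterior skin. For dorsal posterior skin 2 mixed splits within numbers were also as large as the real one. It mixed libraries of different locations for the saddle, ventral-most and ventral posterior skin, and a mixed split gave 160 genes for the difference. Splits with several times the real count occurred for the saddle and ventral-most skin, and what those splits follow was not tested. For the 2 anterior-posterior contrasts 10 splits are too few for a share under 0.05. The real counts were 318 and 246 and the highest others 1 and 24.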

How the results depend on the processing

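The replicate number as a random effect was tried only after the results had been seen. No named call changed direction under any alternative run. For genes ranked by fold change this was partly fixed in advance, because the naming rule required the same sign within each replicate number. Leaving out a number could therefore not turn them, and the replicate block leaves fold changes as they are in this balanced design. Of 218 named gene results 207 were called, and 82 of these kept their call in every alternative. The other 125 lost it in 1 or more: 121 on leaving out a replicate number, 61 on leaving out a single library, 22 with edgeR, 4 with DESeq2, 50 in a fit of the compared libraries alone, 11 without the filter, 6 and 5 with pseudocounts of 0.5 and 8, 8 with quantile normalization, 6 of the dorsal-ventral calls without the flank, and 0 under the replicate block. Counts moved more, and the balance of higher against lower calls turned in 30 of 252: 23 leaving out libraries or numbers, 3 in the fit of the compared libraries alone, 2 with the block (ventral anterior 436 and 448, ventral posterior 222 and 256), 1 with the random effect, and 1 with edgeR (ventral-most, 53 and 34 against 40 and 55). In the order any difference, dorsal against ventral, dorsal and ventral anterior-posterior contrasts, their difference, dorsal anterior, saddle and posterior, ventral-most, flank, ventral anterior and ventral posterior, the numbers 2152, 2409, 318, 246, 116, 287, 20, 121, 95, 427, 420 and 154 became 4208, 4084, 740, 589, 411, 610, 57, 475, 339, 1021, 884 and 478 with the replicate block, which removes variance shared by a number. From the second on they became 3894, 719, 603, 418, 588, 64, 435, 344, 991, 882 and 485 with the number as a random effect. DESeq2 gave 3462 for any difference and 598, 499, 380, 518, 93, 379, 316, 774, 751 and 403 from the third on. A fit of the compared libraries alone, which has fewer samples, gave 128, 41, 34 and 142 for the contrasts, their difference and dorsal anterior, and 69, 35, 228, 257 and 86 from dorsal posterior on. Without the filter the saddle had 11 calls, and the cause was not tested, as for DESeq2. Leaving out libraries, where fewer samples remain, gave ranges of 244 to 2187, 813 to 2457, 26 to 276, 27 to 305, 0 to 148, 29 to 277, 0 to 26, 3 to 135, 0 to 137, 17 to 483, 34 to 439 and 6 to 226 in the same order. The ends at 0 are limma counts, where 338 to 1194 genes had an unadjusted p below 0.05, and edgeR on all libraries called 100, 14 and 87. Without the flank 2244 genes were called between dorsal and ventral skin. List tests were repeated with the block, quantile normalization and an estimated correlation, and the calls these changed are beside each list. The median log2 fold change of all genes lay within 0.026 of 0 under every setting. After thinning all libraries to 12.9 M reads limma called 2364 genes between dorsal and ventral skin, so unequal depth moved that count little. Depth limits ratios against 3 or fewer reads. In simulated data without an effect of the replicate number, 31.3% of genes changed 1.5-fold were recovered with 9 against 12 libraries, and 3% with 3 against 3. A location left with 2 libraries is assumed to vary like the others.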

Other observations

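The test of replicate numbers in this part was chosen only after the results had been seen.

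Further genes were higher at 1 ventral location than at the others of that side. VIPR2 (GSZG0005400), a receptor for a vasoactive peptide, averaged 6876 ± 2645 in ventral-most skin (SD, n = 3) and 711 ± 363 in ventral posterior skin, the next highest mean, with a log2 fold change of 4.26 (SE 0.69, adjusted p = 0.00594) against the other ventral locations. HOXB8 was higher there too (4.0, SE 0.66). Leaving out ventral-most replicate 3 or 8 ended both calls, with values of 4.23 and 3.98 for VIPR2 and 3.83 and 3.94 for HOXB8. ISL1 averaged 1016 ± 923 in ventral posterior skin (4.73, SE 0.76), a call that ended without ventral posterior replicate 8 (3.98). The homeobox gene ONECUT1 averaged 751 ± 308 in flank skin (5.57, SE 1.11, adjusted p = 0.0101), a call that ended without flank replicate 8 (5.25) or in a fit of the compared libraries alone.

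C1QTNF3 averaged 3879 ± 1013 in dorsal anterior skin and 692 and 596 in the other dorsal locations, and no ventral mean was above 260. It was higher dorsally with a log2 fold change of 4.94 (SE 0.80, adjusted p = 0.000288). The keratan sulfate proteoglycan gene KERA, whose symbol comes from the deposited name alone, averaged 12070 ± 5968 in ventral anterior skin and 1687 ± 579 in the dorsal saddle.

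Between replicate numbers, after location means were removed, 6676 of 14005 genes differed by limma, and lists as a whole were not tested. Of 9 macrophage genes 6 differed between numbers (median deviation -0.25, -0.15 and 0.55 for numbers 3, 8 and 11), of 18 melanocyte genes 9 (-0.37, 0 and 0.32), of 15 hypoxia genes 11 (0.10, 0.09 and -0.18) and of 22 cell cycle genes 16 (-0.02, 0.14 and -0.16). Counts were low for endothelium (1 of 12) and epidermis (2 of 11). Limma called 0 of 16 skeletal muscle genes, 0 of 7 HOX genes in groups 9 to 13 and 0 of 6 mesothelium and kidney genes, also 0 at an unadjusted p below 0.05, and no other tool was run for these.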
